A study of Mus musculus with 18 samples.

How the data were processed

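Libraries were made from 30 ng of total RNA with a kit that primes at the poly(A) tail and sequences near the 3′ end of transcripts, and only read 1 of each pair was used, per the labels' protocols. Counts therefore measure the end of a transcript and need no length correction. The deposited tables hold whole-number read counts per gene, which the authors did not normalize as far as the values show. FastQC 0.12.1, STAR 2.7.10b, HTSeq 0.11.3 and the genome build GRCm38 are listed per the submitters' processing notes. The gene annotation, the strand setting of the counting and the handling of duplicate reads are not given in the sources used here. The protocol names no molecular identifiers, so reads copied from 1 molecule in amplification are not told apart, and intervals or spreads from read counts cover more than sampling.

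The tables list 46983 gene names, of which 40115 matched the GENCODE M21 annotation of GRCm38 directly, 4029 matched after restoring characters that had been altered in the deposited names, and 2839 were unmatched. Chromosome positions are 1-based and come from that annotation. Genes that overlap on opposite strands cannot be told apart, since the strand setting is not given. Samples were grouped by tissue and treatment labels. 1 bone marrow column carries a number pair that is in no sample title, but its prefix names the glutamine arm. One of its numbers is in the glutamine title left without a column, and the other is in an HFD title. It was used as a library of that arm and is called unnumbered here, and its identity stays open. All 18 libraries were used.

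Each tissue was tested on its own 9 libraries with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM factors, a quasi-likelihood fit and a two-sided F test with Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. The difference of the glutamine effect between tissues and the difference between tissues were tested in 1 fit of all 18 libraries with 4 groups. The standard error of a log2 fold change was taken as its absolute value divided by the square root of F. Printed CPM levels are relative to a library's total count without further scaling, while the overlap of arms and the list scores used TMM-scaled log2 CPM or CPM. For genes near 0 counts in 1 arm the fitted fold change depends on the prior count.

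Gene lists of metabolic pathways, stress responses, signalling targets, skeletal and adipose cell types, leukocytes, vessels and other possible contaminating cells were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, where at least 5 members were tested. List scores are the mean log2 CPM of a list in a library, compared by exact permutation over the 126 splits of 9 libraries into 4 and 5. The lists, the edgeR and camera tests and the alternatives, apart from those said to be added, were chosen before the data were examined, and the list scores were added afterwards. The named genes of each tissue were up to 8 per direction past the threshold with the largest changes, an average log2 CPM of at least 1 and no overlap between arms, filled up to 4 with the smallest p where fewer passed in a direction, together with the 3 leading members of up to 6 passing lists and a fixed panel of 15 genes, of which 1 is not reported here but stays in counts over the panel and its lists. For the difference of effects the 4 smallest adjusted p per direction were named, and between tissues the 5 largest changes per direction at an average log2 CPM of at least 4. Predicted or unnamed gene models were counted but not named.

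The alternatives were relative log expression and upper-quartile factors, no count filter and a stricter one, DESeq2 1.42.0, limma-voom with quality weights, robust fitting, the joint fit, a block on the shared replicate label, and leaving out each library. Counts under 100 set to 0, abundant genes alone, and fits without doubted libraries were added after the data were seen.

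The tests were tried on simulated counts with the real library sizes and gene means, 100 genes changed 4-fold and 100 changed 16-fold. With each gene's fitted dispersion, whose median was 0.378 in adipose and 3.32 in bone marrow, 49% and 54% of these genes were recovered in adipose among 14634 genes tested, and none in bone marrow among 5962. For the difference between the tissues' effects none were recovered among 14725 genes, and between tissues 2% and 11% among 14895. With a dispersion of 0.1, recovery was 100% and 99% in bone marrow, 98% and 99% in adipose, and 97% and 100% between tissues, but 59% and 76% for the difference of effects. The required recovery for 16-fold changes was lowered once to admit that last value. Of 20 unchanged lists in the simulations none were called in either tissue, and the shifted list was found in both. Genes were drawn independently there, so these lists do not test false calls where members vary together. In the real adipose data the estimated correlation of the macrophage list was 0.396. The common dispersion of the real data, 1 value over all genes, was 3.08 in bone marrow and 0.908 in adipose, and library totals were 13970788 to 37984603 counts in bone marrow and 35871168 to 59529238 in adipose.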

Results

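RNA was sequenced from bone marrow and adipose samples of male C57BL/6J mice, an inbred laboratory strain. The sample descriptions carry HFD, and 1 arm of each tissue was given glutamine, the most abundant free amino acid in blood. The series title places the question in obese mice and asks about glutamine, skeletal strength and fitness. Sample titles of the bone marrow libraries read mBMSC and those of the adipose libraries mAT-MSC VAT. Each tissue had 9 libraries, 4 from the HFD arm and 5 from the HFD arm with glutamine, 18 in all. Each sample description carries a pair of numbers, and the same pairs occur in both tissues. The labels do not say what these numbers stand for, or that the libraries of an arm came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

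The adipose libraries held 35871168 to 59529238 counts and the bone marrow libraries 13970788 to 37984603. Genes with at least 100 counts numbered 12769 ± 878 (SD, n = 9) per adipose library and 3525 ± 1700 (SD, n = 9) per bone marrow library. In bone marrow this number ran from 1755 to 7323. The gene of the collagen I alpha 1 chain, Col1a1 (chromosome 11, 94936224 to 94953042), took 12.7% ± 6.09 (SD, n = 9) of the bone marrow counts and 0.699% ± 0.143 (SD, n = 9) of the adipose counts. Log-scale correlations across genes between pairs of libraries ran from 0.422 to 0.646 within bone marrow and from 0.903 to 0.969 within adipose. Of the genes with at least 100 counts in any library of a tissue, 263 reached that level in all 9 bone marrow libraries and 3239 in exactly 1. The same numbers in adipose were 8790 and 2829.

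**Figure D1:**
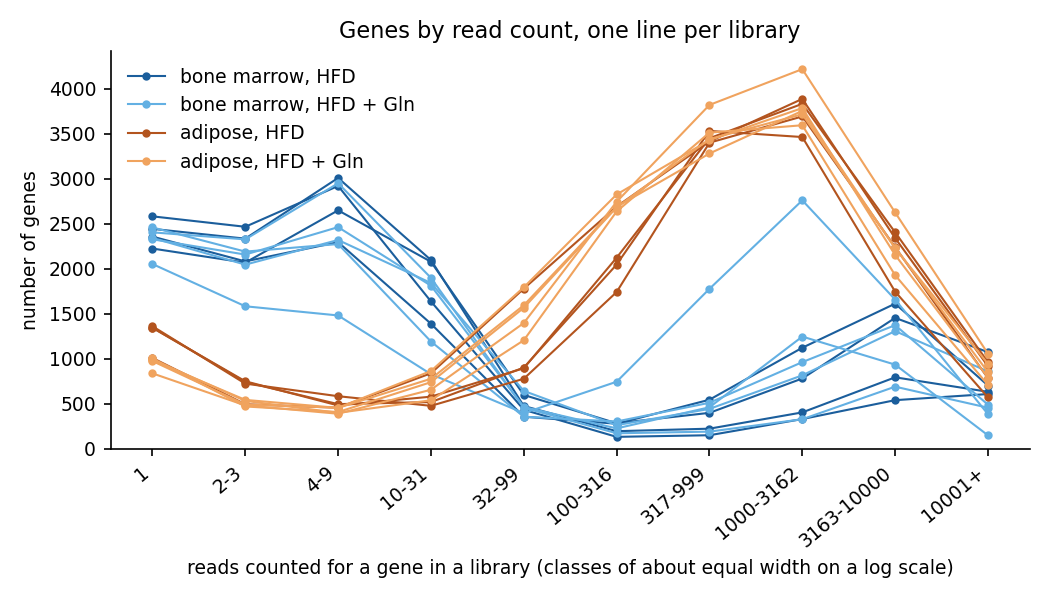
Number of genes (vertical axis) in each class of read count (horizontal axis, classes of about equal width on a log scale), with 1 line per library coloured by tissue and arm. Bone marrow libraries had many genes under 32 counts, few from 32 to 316, and a separate set above 1000. Adipose libraries had their largest maximum above 316 counts and a smaller one at 1 count. The bone marrow line that stands apart is the glutamine library 18_20, with 7323 genes at 100 or more counts.

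The first comparison set adipose against bone marrow and describes what each kind of sample held. Tissue, isolation and count table went together, so their parts in a difference cannot be told apart. Genes of bone and of granulocytes were higher in bone marrow. Bglap, which encodes osteocalcin of the bone matrix, differed by -11.51 ± 1.06 (log2 adipose over bone marrow ± SE, n = 9 per tissue). Its level was 2048 ± 2611 CPM (SD, n = 4) in bone marrow HFD libraries and 2.58 ± 0.290 CPM (SD, n = 4) in adipose HFD libraries. The granule protein genes Ngp and Camp differed by -11.36 ± 0.886 and -11.39 ± 1.16. The fibrillar collagen gene Col24a1 differed by -11.75 ± 2.08 and Nfe2, a transcription factor of the erythroid and megakaryocyte lineages, by -11.40 ± 2.12. Among genes higher in adipose were Cadm3 at 6.63 ± 0.828, an adhesion molecule, and the chemokine genes Ccl7 at 6.38 ± 0.913 and Pf4 at 6.34 ± 0.854. Slfn5 followed at 6.36 ± 0.838 and H2-Eb1, an MHC class II chain, at 6.34 ± 0.90. The edgeR adjusted p of these 10 genes was at most 0.000152.

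**Figure D2:**
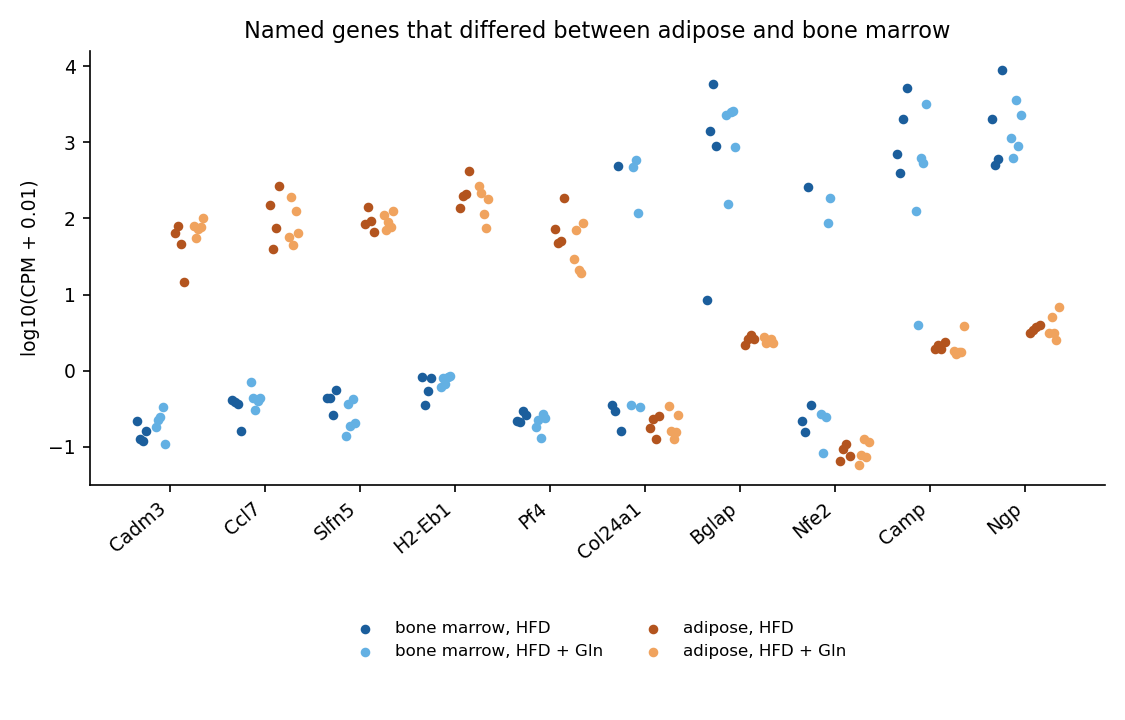
Level of the 10 named genes that differed between tissues, as log10(CPM + 0.01) on the vertical axis, with 1 point per library for the 4 groups. Each of the 5 genes higher in adipose lay under 1 CPM in all 9 bone marrow libraries, and several bone marrow libraries had Col24a1 and Nfe2 at the adipose level.

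In all, 7858 of 15203 genes differed between tissues (edgeR, adjusted p under 0.05), 6150 higher in adipose and 1708 lower. The split between directions depended on the scaling. With relative log expression factors 2465 were higher and 6524 lower, with upper-quartile factors 3222 and 5144, and with DESeq2 2063 and 4832. The median log2 difference of all genes was 1.43 with TMM factors, -1.94 with relative log expression factors and -0.89 with upper-quartile factors, so gene lists are given relative to it. The directions of the 10 named genes held under these scalings. Their sizes are not relative to that median and shift with the scaling, which the SE does not cover. Bglap lies beside a near-identical copy and is reported as uncertain.

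Of 43 gene lists, 20 passed camera's competitive test between tissues, 7 toward adipose and 13 toward bone marrow, and 10 passed with an estimated correlation. The osteoblast list had a median of -8.13 relative to all genes, with 12 of 13 members negative and 11 called (adjusted p = 1.50e-14, and adjusted p = 0.00415 with an estimated correlation). The chondrocyte list stood at -12.32 relative to all genes (adjusted p = 1.47e-13), the neutrophil list at -10.99 (3.13e-13) and the marrow stroma list at -5.01 (6.13e-09). The erythroid list stood at -3.93 (1.24e-06), mitosis at -6.19 (2.54e-11), DNA replication at -6.20 (3.82e-07), ribosomal proteins at -3.07 (8.88e-17) and mitochondrially encoded genes at -5.12 (1.66e-10). With an estimated correlation these calls held at adjusted p between 0.00583 and 0.0198. Toward adipose, the adipose progenitor list stood at 2.10 (adjusted p = 0.00141, and adjusted p = 0.0211 with an estimated correlation). The endothelial list at 4.09, T and NK cells at 4.59, MHC class II at 4.35, mesothelial at 4.6, B and plasma cells at 4.52 and mural cells at 1.54 passed only with the preset correlation. With an estimated correlation their adjusted p ranged from 0.140 for the endothelial list to 0.420 for the mesothelial list. The respiratory chain list at -3.09, the matrix list at -1.79, the tricarboxylic acid cycle at -2.81 and MHC class I at -3.18 likewise passed only with the preset correlation, with adjusted p = 0.0521, 0.318, 0.239 and 0.318 with an estimated correlation. The mural and MHC class I lists did not pass under the other scalings, with adjusted p = 0.0963 and 0.0570 under relative log expression factors. The other lists did not pass with TMM factors, among them macrophage at 2.29 (adjusted p = 0.117), adipocyte at 2.15 (0.309), osteoclast at 2.39 (0.254) and glutamine metabolism at -1.35 (0.360). The immediate early list passed as lower than other genes under relative log expression (adjusted p = 0.0102) and upper-quartile factors (0.0425), and the unfolded protein response list under relative log expression factors (0.0159).

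The second comparison asked which bone marrow genes differed with glutamine. Transcripts of 8 genes fell with glutamine and none rose among 6041 tested (edgeR, adjusted p under 0.05), of which 6 have gene names. Ndufa7, a subunit of respiratory complex I (chromosome 17, 33824572 to 33838317), had 489 ± 770 CPM (SD, n = 4) with HFD and 0.971 ± 0.268 CPM (SD, n = 5) with glutamine, a log2 fold change of -10.17 ± 2.29 (SE, adjusted p = 0.0378). Nt5e, the surface enzyme CD73 that makes adenosine (chromosome 9, 88327197 to 88372092), fell by 10.19 on the log2 scale (SE 2.48). Snx14, its neighbour on the chromosome (88376750 to 88438958), fell by 10.80 (SE 2.64). Frmd8 (chromosome 19, 5849702 to 5875274) fell by 8.50 (SE 2.03), the sister chromatid cohesion factor gene Cdca5 (chromosome 19, 6084983 to 6091777) by 8.45 (SE 2.05; 2.69 higher without HFD library 23_28), and the serum response factor coactivator gene Mkl1 by 10.69 (SE 2.68, adjusted p = 0.0498).

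The arms overlapped for each of these 6 genes, so they fall outside the rule for named genes and were chosen after their values were seen. At least 100 counts were found in 3 of 4 HFD libraries for Ndufa7 and Nt5e, in 2 for Frmd8 and Mkl1, and in 1 for Cdca5 and Snx14. No glutamine library reached 100 counts for Ndufa7, Nt5e, Snx14 or Mkl1, and 1 of 5 did for Frmd8 and Cdca5.

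**Figure D3:**
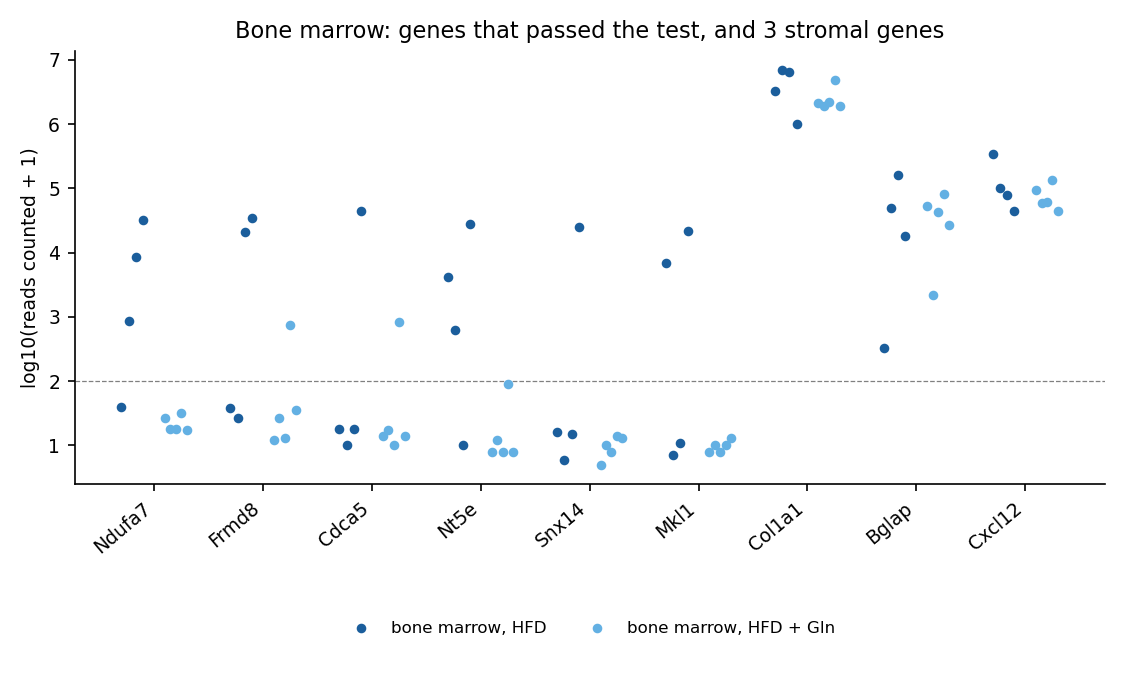
Reads counted per bone marrow library, as log10(count + 1) on the vertical axis, for the 6 named genes that passed the test and for Col1a1, Bglap and Cxcl12, with 1 point per library (4 HFD, 5 HFD with glutamine) and a dashed line at 100 counts. The 6 genes were under 100 counts in most libraries and reached up to 44674 counts in single HFD libraries, whereas the 3 stromal genes had at least 321 counts in every library.

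Among genes whose arms did not overlap in TMM-scaled CPM, Itch, a ubiquitin ligase gene, had 362 ± 455 CPM (SD, n = 4) with HFD and 0.626 ± 0.174 CPM (SD, n = 5) with glutamine, a log2 fold change of -10.17 ± 2.63 (SE) that did not pass (edgeR adjusted p = 0.0562). Anxa5, which encodes the phosphatidylserine-binding annexin A5, had 522 ± 151 CPM (SD, n = 4) and 17.0 ± 29.8 CPM (SD, n = 5), with a log2 fold change of -6.15 ± 2.10 (adjusted p = 0.197). Tusc2 at -9.11 ± 2.93 and the myeloid kinase gene Fgr at -9.30 ± 3.21 had the same adjusted p. In CPM without scaling the arms of Itch, Tusc2 and Fgr overlapped, with the lowest HFD library at 0.536, 0.397 and 0.248 CPM and the highest glutamine library at 0.801, 1.22 and 0.358. In the other direction, the nonsense-mediated decay factor gene Upf3b at 9.60 ± 2.51 had an adjusted p of 0.0570, and Lrrc59 at 8.73 ± 2.80, Rpap3 at 7.5 ± 2.41 and the kinesin gene Kif22 at 9.73 ± 3.28 had 0.197. Lrrc59 reached 453 counts or more in each of the 5 glutamine libraries and at most 31 in the 4 HFD libraries. In all, 151 genes had arms without overlap in TMM-scaled CPM, 2.50% of those tested, where chance gives 1.59% on average over splits. The spread of this share between splits was not computed, so an excess was not tested.

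Of the fixed panel, Col1a1 had a log2 fold change of -0.80 ± 0.213 (SE, adjusted p = 0.0737) with glutamine in bone marrow. Tested among the 86 most abundant genes alone, the same change had an SE of 0.632 and an adjusted p of 0.693, and its share of counts gave p = 0.587 in an exact permutation test. It passed with limma-voom (adjusted p = 0.00627) and without HFD library 1_3 or 23_28 or the unnumbered glutamine library (adjusted p = 0.0184, 3.79e-13 and 0.0159). The 2 thinnest libraries, with the fewest genes at 100 or more counts, were HFD library 23_28 and the unnumbered glutamine library. Without them Col1a1 stood at -1.46 (edgeR adjusted p = 2.46e-38). Its share of counts overlapped between the arms left, at 8.74% to 23.0% with HFD and 6.18% to 15.8% with glutamine. Neither this adjusted p nor the 3.79e-13 reflects that spread. Col1a1 stood at -0.15 without HFD library 14_17 (adjusted p = 0.868), -0.30 without glutamine library 25_27 (0.782), -0.40 without glutamine library 4_6 (0.701) and -0.12 with upper-quartile factors (0.985). Bglap stood at -1.05 ± 1.00, the stromal chemokine gene Cxcl12 at -0.57 ± 0.843, the osteoblast genes Runx2 at 0.14 ± 2.09 and Alpl at 1.41 ± 2.18, and the adipokine gene Adipoq at -0.69 ± 1.80. Glutamine synthetase, Glul, stood at 2.40 ± 2.40, and the glutamine transporter genes Slc1a5 at -0.92 ± 2.16 and Slc38a2 at -1.39 ± 1.54. Cebpa stood at -3.73 ± 2.48 and Cdkn1a at -2.08 ± 2.26, and none of these passed. Sp7, Pparg and Il6 were below the count filter in bone marrow. Sp7, an osteoblast transcription factor gene, reached 100 counts in 1 of 4 HFD and 2 of 5 glutamine libraries.

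None of the 35 bone marrow gene lists passed (camera, lowest adjusted p = 0.815, and 0.957 with an estimated correlation). Cholesterol synthesis had the smallest unadjusted p at 0.0233, with all 7 tested members positive, a median log2 fold change of 2.41 and 1 member called adjusted over the list alone. The osteoblast list had a median of -0.29, chondrocyte 0.96, marrow stroma -0.58, adipocyte -0.55 (mean 0.09), neutrophil -1.24, macrophage -0.38 and glutamine metabolism 0.70. At least 1 member was called adjusted over the list alone in 7 lists.

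The bone marrow count rested on single libraries and on the tool. No gene was called with relative log expression or upper-quartile factors, with robust fitting, or without any 1 of the glutamine libraries 4_6, 10_12, 18_20 and 25_27. Without HFD library 23_28, which had the highest HFD level of each of the 6 named genes, 2 genes were called, 0 of them among the 8. That library had the fewest genes at 100 or more counts in bone marrow, 1755. Its TMM factor, 0.460, was the smallest, which raises its scaled values. There were 14 calls without HFD library 1_3 or 5_11, 19 without 14_17 and 16 without the unnumbered glutamine library. While limma-voom called 1, Col1a1, DESeq2 called 1042, 613 up and 429 down, of which 2 were among the 8. At an unadjusted p under 0.05 there were 1127 genes by edgeR. Other splits of the 9 libraries gave 846 to 1829, so this number does not set the real arms apart.

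The third comparison asked the same of adipose. The macrophage and MHC class II lists were lower with glutamine and the mural and endothelial lists were higher, with no single gene passing and no list passing with an estimated correlation. Both vessel lists lost their call without HFD library 23_28 (adjusted p = 0.292) and without glutamine library 13_15 (0.0539 for mural, 0.10 for endothelial) or 25_27 (0.162 and 0.213). The macrophage list had a median log2 fold change of -0.97 with all 16 tested members negative (camera adjusted p = 5.47e-09, and adjusted p = 0.583 with an estimated correlation), and 5 members were called adjusted over the list alone. C1qc, a complement component made by macrophages (chromosome 4, 136889804 to 136893065), had 62.8 ± 36.7 CPM (SD, n = 4) with HFD and 21.5 ± 12.2 CPM (SD, n = 5) with glutamine, a log2 fold change of -1.58 ± 0.461 (SE). Ptprc, the pan-leukocyte surface protein CD45 (chromosome 1, 138062861 to 138175708), had 166 ± 96.8 and 73.3 ± 12.3 CPM, a log2 fold change of -1.20 ± 0.314, with arms that did not overlap in TMM-scaled CPM but did without scaling, where the lowest HFD library had 86.9 CPM and the highest glutamine library 88.5. Lyz2, the lysozyme gene, stood at -1.20 ± 0.378. The edgeR adjusted p of each of these genes over all genes tested was 1.00 after rounding.

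The MHC class II list had a median of -0.75 with all 7 members negative (adjusted p = 2.78e-05, and adjusted p = 0.583 with an estimated correlation, 3 called adjusted over the list alone). H2-Aa stood at -1.12 ± 0.360, H2-Ab1 at -1.02 ± 0.365 and the invariant chain gene Cd74 at -0.73 ± 0.220. The B and plasma cell list had a median of -0.58 with all 8 members negative (adjusted p = 0.0106, and adjusted p = 0.622 with an estimated correlation), and its immunoglobulin genes Ighm and Jchain stood at -1.52 ± 0.541 and -1.27 ± 0.478 and Mzb1 at -0.79 ± 0.725. The T and NK cell list had a median of -1.08 with 9 of 11 negative (adjusted p = 0.0378, and adjusted p = 0.626 with an estimated correlation, 1 called adjusted over the list alone). The inflammation list had a median of -0.47 with 13 of 18 negative (adjusted p = 0.0132, and adjusted p = 0.626 with an estimated correlation). Its median was 0.0497 without HFD library 23_28 and glutamine library 25_27, and its score gave p = 0.603 in an exact permutation test. The list held the cytokine gene Il1b at -2.00 ± 0.674, the NF-kB inhibitor gene Tnfaip3 at -1.20 ± 0.415 and the adhesion gene Icam1 at -0.57 ± 0.261. The list of stromal regulators of osteoclasts had a median of -0.44 with 9 of 10 negative (adjusted p = 0.0407, and adjusted p = 0.622 with an estimated correlation), mitosis -0.31 with 15 of 18 negative (adjusted p = 0.0384, and adjusted p = 0.626 with an estimated correlation) and ribosomal proteins -0.20 with 39 of 48 negative (adjusted p = 3.80e-05, and adjusted p = 0.583 with an estimated correlation). Rps29, Rpl11 and Rpl30 stood at -0.37 ± 0.133, -0.45 ± 0.163 and -0.54 ± 0.210, and ribosomal protein genes have many near-identical pseudogenes that the counting could mix. The mural list had a median of 0.77 with 7 of 8 positive (adjusted p = 0.0132, and adjusted p = 0.626 with an estimated correlation), led by the pericyte proteoglycan gene Cspg4 at 3.45 ± 1.35, with Notch3 at 0.85 ± 0.452 and Abcc9 at 0.76 ± 0.426. The endothelial list had a median of 0.50 with 10 of 11 positive (adjusted p = 0.0132, and adjusted p = 0.626 with an estimated correlation).

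**Figure D4:**
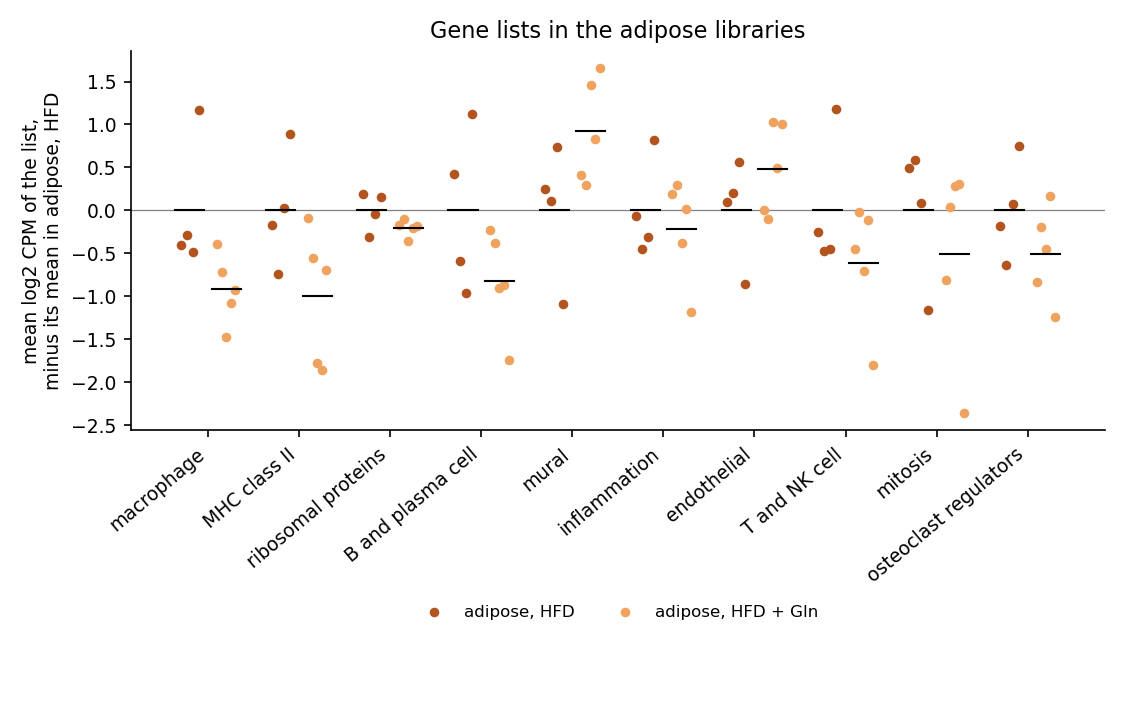
Mean log2 CPM of each of the 10 adipose gene lists that passed the preset-correlation test, per library, minus the mean of the 4 HFD libraries (vertical axis), with 1 point per library and a bar at the mean of each arm. The HFD library 23_28 lies above the other 3 HFD libraries in the macrophage list, and the glutamine mean lies 0.918 below the HFD mean there.

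These 10 of 43 lists passed with camera's preset correlation of 0.01, 2 up and 8 down. None passed with an estimated correlation, where the smallest adjusted p was 0.583, or with fry, where it was 0.201. An exact permutation test of the macrophage list's mean log2 CPM per library gave a difference of -0.918 between arms (n = 4 and n = 5, two-sided p = 0.0317, adjusted p = 0.341 over 43 list scores). The exact p of the scores was 0.0873 for mural, 0.111 for MHC class II, 0.127 for ribosomal proteins, 0.183 for B and plasma cells, 0.206 for osteoclast regulators, 0.238 for endothelial, 0.365 for T and NK cells and 0.540 for mitosis. HFD library 23_28 had the highest macrophage and T and NK cell scores, and 5 lists were called without it, 4 of them among the 10. Without glutamine library 25_27 there were 4, of which 3 were among the 10, and likewise 4 and 3 without both libraries. Without HFD library 23_28 or without glutamine library 25_27 the inflammation, T and NK cell, B and plasma cell, osteoclast regulator, mural and endothelial calls were lost, and mitosis was lost without HFD library 1_3 or 5_11 or glutamine library 4_6 or 25_27. The osteoclast regulator call was also lost without glutamine library 4_6 or 13_15. The T and NK cell and B and plasma cell medians were 0.15 and 0.07 without both libraries. The macrophage, MHC class II and ribosomal protein lists passed in each of these fits, with macrophage medians of -0.64, -1.04 and -0.78.

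The other adipose lists did not pass. The respiratory chain list had a median of -0.11 (adjusted p = 0.118) and interferon-stimulated genes 0.29 (0.172). Glutamine metabolism stood at -0.04 (0.327), the tricarboxylic acid cycle at -0.10 (0.231), glycolysis at 0.02 (0.576), mitochondrially encoded genes at -0.30 (0.321), antioxidant genes at -0.13 (0.327), ATF4 targets at 0.01 (0.90) and the unfolded protein response at -0.07 (0.308). Among lipid lists, cholesterol synthesis stood at 0.09 (0.506), lipogenesis at 0.02 (0.824), fatty acid oxidation at -0.01 (0.944), adipocyte at 0.20 (0.824) and thermogenic at -0.50 (0.920). Adipose progenitor stood at 0.14 (0.949), mesothelial at 0.33 (0.90), neutrophil at -0.29 (0.271), erythroid at -0.24 (0.448), osteoblast at -0.02 (0.626), osteoclast at -0.29 (0.576), chondrocyte at -0.13 (0.889) and marrow stroma at 0.03 (0.748). Matrix stood at 0.11 (0.231), myofibroblast at 0.12 (0.714), WNT at -0.12 (0.889), BMP at 0.22 (0.949), insulin and IGF at 0.24 (0.327), hypoxia at -0.01 (0.824), p53 and senescence at 0.03 (0.940), immediate early at -0.08 (0.539), lysosome at 0.09 (0.512), DNA replication at -0.08 (0.231) and MHC class I at -0.18 (0.327). The median, mean and test differed in sign for the osteoblast, hypoxia, lipogenesis, mesothelial, thermogenic, fatty acid oxidation, ATF4, chondrocyte and adipose progenitor lists. The epithelial and skeletal muscle lists had fewer than 5 members tested.

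No adipose gene was called by edgeR among 15114 tested, with 624 at an unadjusted p under 0.05. DESeq2 called 184, 148 up and 36 down, and limma-voom called 0. Genes without overlap between arms in TMM-scaled CPM numbered 253, 1.67% of those tested, where chance gives 1.59% on average over splits. Named by the smallest p, and not passing, were Atp6ap2, a proton pump accessory protein gene, with 124 ± 3.95 CPM (SD, n = 4) and 196 ± 18.7 CPM (SD, n = 5) and a log2 fold change of 0.65 ± 0.165, and Hif1an, which encodes an inhibitor of HIF-1, at 1.53 ± 0.407. Lilrb4a, a myeloid inhibitory receptor gene, stood at -1.49 ± 0.377 and H2-T23, an MHC class I gene with close paralogs and hence uncertain, at -5.70 ± 1.43. Igfals had 57 to 656 counts in HFD libraries and at most 1 in glutamine libraries (edgeR adjusted p = 0.687). Spef2 had 0 to 2 counts in HFD libraries and 28 to 396 in glutamine libraries, and Piwil2 0 to 1 and 13 to 945.

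Of the panel in adipose, Glul stood at 0.22 ± 0.167, Slc1a5 at 0.07 ± 0.203 and Slc38a2 at -0.01 ± 0.198. The adipogenic regulators Pparg and Cebpa stood at -1.27 ± 0.609 and -0.30 ± 0.377, Adipoq at -0.22 ± 0.482, Il6 at -0.34 ± 0.266, Cxcl12 at -0.03 ± 0.343, Cdkn1a at -0.07 ± 0.230 and Col1a1 at 0.30 ± 0.171. Runx2 stood at -0.17 ± 0.858, Alpl at 0.69 ± 0.394 and Bglap at -0.08 ± 1.10. None passed, and Sp7 was below the count filter.

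The fourth comparison asked whether glutamine's effect differed between tissues. Aspn, which encodes the matrix proteoglycan asporin (chromosome 13, 49544443 to 49567565), had 218 ± 65.0 CPM (SD, n = 4) in bone marrow with HFD and 2.49 ± 2.36 CPM (SD, n = 5) with glutamine, against 284 ± 46.5 and 282 ± 34.9 CPM in adipose, a difference of effects of 6.97 ± 1.32 (log2 ± SE). Acan, the aggrecan gene of cartilage (chromosome 7, 79053483 to 79115099), had 0.108 ± 0.0418 and 155 ± 125 CPM in bone marrow and at most 9 counts in any adipose library, a difference of -11.70 ± 2.17. Ndufa7 differed by 9.81 ± 1.94, Itch by 9.30 ± 1.93 and Snx12 by 9.13 ± 1.99, and Pdp2 by -10.14 ± 1.85, Lrrc59 by -8.65 ± 1.57 and Tmem123 by -8.34 ± 1.54. The edgeR adjusted p of each of these 8 was 0.0432. Only Ndufa7 among them was called in the test of bone marrow alone. This fit of 18 libraries shared its dispersions between tissues. Its common dispersion was 2.03, against 3.08 in bone marrow alone and 0.908 in adipose alone. In the same fit 3926 bone marrow genes were called with glutamine, against 8 in bone marrow alone. These p-values therefore do not measure the spread of bone marrow by itself.

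In all, 1811 of 15203 genes passed, 615 up and 1196 down. More genes were up than down without bone marrow HFD library 1_3 (336 and 106), 5_11 (330 and 136) or 14_17 (313 and 86). The count was 0 with relative log expression or upper-quartile factors and with a block on the replicate label shared by both tissues. It was also 0 without any 1 of the 9 adipose libraries, and without bone marrow HFD library 23_28. It was 442, 466 and 399 without bone marrow HFD libraries 1_3, 5_11 and 14_17, 3 with limma-voom and 1083 with DESeq2. No list passed for the difference (0 of 43, camera). Across the 6014 genes tested in both tissues, the fold changes with glutamine had a Pearson r of 0.0305 (Spearman rho 0.0482), and genes are not independent replicates. Without label 23_28 r was 0.00777.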

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

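The tests of few captured molecules, of both sources of low counts, of a single leukocyte-rich library and of a smaller leukocyte share were chosen only after the results they address were seen, and the macrophage score test was not among the tests fixed in advance. A gap rule for single samples picked 8 of 136 groups, 5.88%, where chance picks about 1 in 20.

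The test of the difference itself called a glutamine effect that differed between tissues for 21 genes named here, with edgeR adjusted p from 0.0432 to 0.0487. All were picked by their values in these same libraries, so the test gives no independent support. For genes named from bone marrow the log2 differences, adipose minus bone marrow, were Upf3b -9.74, Lrrc59 -8.65, Rpap3 -7.62, Kif22 -11.47, Itch 9.30, Tusc2 9.0, Anxa5 5.84, Fgr 6.88, Ndufa7 9.81, Frmd8 8.13, Nt5e 9.51, Snx14 9.24 and Mkl1 10.60. For genes named from adipose they were Spef2 12.48, Hif1an 6.47 and Igfals -15.58, fitted values that depend on the prior count where an arm is near 0. For genes named from the difference itself they were Aspn 6.97, Snx12 9.13, Pdp2 -10.14, Tmem123 -8.34 and Acan -11.70. These calls end with relative log expression factors, and 10 of 100 splits made separately in each tissue gave as many genes as the real 1811, with up to 2236 in another split, so chance cannot be excluded. In splits of the 8 labels found in both tissues, the real split gave 0 genes, so all 35 splits gave as many by construction, and the highest other gave 9.

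The 8 genes called in bone marrow had on and off counts. Of 100 splits of the 9 libraries, 33 called as many genes, with up to 31 in another split, so chance cannot be excluded. A candidate explanation is that few molecules were captured per gene. Among the 473 bone marrow genes at the level of the called genes, 23.8% of counts were under 100 while 70.1% were above 1000, and in adipose none of the counts at that level were under 100, as that explanation needs. Genes at 100 counts or more in every library of one arm and none of the other numbered 5, and 110 of 126 splits gave as many, with up to 74. An effect of glutamine on these genes stays open and is not separated from this.

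Low counts in bone marrow followed adipose levels. Over 673 to 2706 genes per bone marrow library with 20000 to 100000 adipose counts, counts under 100 had a Spearman correlation of 0.509 to 0.665 with the adipose total, and at most 0.340% were 0. Reads given to another library after amplification were considered at 1 rate for every library in both directions. Shares per receiving read were then to lie within 3 times of each other over the 18 libraries. The largest was 3.70 times the smallest, with 41 genes in the reverse direction. That bound was passed only through glutamine bone marrow library 10_12. Residuals in the reverse direction reached 6.79 in glutamine adipose library 25_27 and at most 2.27 in the other adipose libraries. Passing the bound and the residual of 6.79 each rested on 1 library. Shares per receiving read also differed by direction, at 9.08 to 22.0 in bone marrow and 5.95 to 9.12 in adipose libraries (relative units). Before division by the receiving library's reads, shares overlapped, at 248 to 528 and 232 to 430 (relative units). The result thus depends on that division, and these values argue at most weakly against a single rate. Rates that differ between libraries were not tested and may account for the low counts. Adipose RNA mixed in before amplification also stays open, because keeping counts under 100 removes the uneven counts it would give, so the largest median squared Pearson residual of 1.62 over the bone marrow libraries decides nothing. No biological explanation was tested.

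Leukocyte lists were lower in adipose with glutamine. Of 100 splits, 13 called as many lists as the real 10, with up to 14, so chance cannot be excluded for the count, and 4 of 126 splits gave a macrophage score difference as large as 0.918, the highest other being 0.970. That share is under 0.05, but the list was picked among 43, and the exact permutation p adjusted over the 43 scores was 0.341, so chance cannot be excluded there either. The score of HFD library 23_28 was 6.08 for macrophages, against 4.42 to 4.63 in the other HFD libraries. For the macrophage list, a single library as the whole cause is argued against by the median of -0.64 without it, although the exact permutation p of the score was then 0.0893. It stays open for the T and NK cell, B and plasma cell and inflammation lists, which lost their calls without that library, with medians of -0.19, -0.15 and -0.10 (camera adjusted p = 0.575, 0.292 and 0.543). A smaller leukocyte share in the glutamine libraries is a candidate explanation, since 90.2% of 51 leukocyte markers had negative fold changes, but most of these markers were in lists already seen to be lower, and a change within the leukocytes or in the tissue stays open.

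Other single values stood apart from their group. Glutamine adipose library 10_12 had 14469 genes at 100 counts or more, against 12385 to 12989. HFD adipose library 23_28 had a T and NK cell score of 4.00, against 2.35 to 2.57, and Mzb1 at a log2 CPM of 4.98, against 3.00 to 3.27. Glutamine adipose library 25_27 had a mesothelial score of -2.45, against 4.14 to 5.15. Lilrb4a was at 4.33 in HFD adipose library 1_3, against 5.40 to 5.47, and Alpl at 5.64 in glutamine adipose library 13_15, against 4.40 to 4.67. In bone marrow with glutamine, Adipoq was at a log2 CPM of 0.27 in library 25_27, against 7.74 to 9.26.

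For the remaining comparisons, 1 of 100 splits, the real one, gave 7858 genes between tissues, with up to 1786 in another split. Chance alone is thus unlikely there, but the splits cannot tell tissue from isolation or count table. The real counts of adipose genes and of bone marrow lists were 0, which 100 of 100 splits meet by construction, and other splits gave up to 2 genes and up to 3 lists. Of 35 splits of the shared labels, 10 gave a correlation of effects as large as the 0.0228 of these labels, with up to 0.0589, so chance cannot be excluded.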

How the results depend on the processing

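Counts under 100 set to 0, abundant genes alone and the fits without doubted libraries were chosen only after the results were seen. The bone marrow genes called (8) became 0 with relative log expression factors, upper-quartile factors, the stricter filter, robust fitting, genes at a log2 CPM of 10 or more, or counts under 100 set to 0, and 1 with limma-voom (Col1a1, not among the 8). Without the filter there were 202 (100 up, 102 down), with DESeq2 1042 (613 up, 429 down, 2 among the 8) and with the joint fit 3926 (2590 up, 1336 down). Leaving out 1 library gave 0 to 19, and 6 were called without the 2 thinnest libraries, none shared with the 8. In adipose, DESeq2 called 184 genes and the other alternatives 0, as in the fit reported. The difference of effects (1811 genes) gave 0 with relative log expression or upper-quartile factors and 0 with the replicate block, 1083 with DESeq2, 3 with limma-voom and 60 with counts under 100 set to 0; leaving out 1 library gave 0 to 2681. The labels do not say what a number shared by both tissues stands for, and the values did not show a pairing: deviations of the 8 shared labels correlated at -0.0175 to 0.0296, which the spread of the bone marrow libraries could hide, and 1 of 8 libraries correlated best with its own label. Between tissues (7858 genes) limma-voom gave 4463 and the block 7448, 7125 higher and 323 lower. Counts under 100 set to 0 gave 7180, 7071 higher in adipose and 109 lower. Leaving out 1 library gave 7020 to 8473. The adipose lists passing (10) were 0 with an estimated correlation or fry and 4 without the 2 doubted libraries, 3 of them among the 10; leaving out 1 library gave 4 to 11. The inflammation list turned to 0.0497 without the 2 doubted libraries. The bone marrow gene Cdca5 ran from -10.88 to 2.69 with 1 library left out, the latter without HFD library 23_28, and was 2.86 without the 2 thinnest libraries. The correlation of effects was 0.0482 as Spearman rho and 0.00777 to 0.0455 with 1 label left out. For all of these the cause was not tested. A value was counted as kept if it stayed on its side of the threshold, where values not called could change sign by a shift within 1 SE. Over the named genes and all alternatives, 371 values were kept in bone marrow, where 65 lost and 24 gained the call. In adipose 689 were kept, and between tissues 265. For the difference of effects 102 were kept, while 114 values lost the call. Read totals alone did not limit the bone marrow test, since simulated changes at a dispersion of 0.1 were recovered at the same totals.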

Other observations

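The test of abundant genes alone and the list scores were chosen only after the data were seen. Among the most abundant bone marrow genes, those with an average log2 CPM of at least 10, the complement regulator gene Serping1 stood at -3.21 ± 1.04 (log2 fold change with glutamine ± SE), the ribosomal protein genes Rps21 and Rps29 at -3.03 ± 1.12 and -2.38 ± 0.937, and the haemoglobin gene Hbb-bs at -1.45 ± 0.808. None of the 86 genes passed when tested alone by edgeR, with 5 at an unadjusted p under 0.05, and the smallest adjusted p was 0.603. Hbb-bs has a near-identical copy and is uncertain.

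In adipose, other list scores that differed before adjustment in the exact permutation test were insulin and IGF at 0.239 higher with glutamine (p = 0.0159), hypoxia at 0.543 (p = 0.0238) and matrix at 0.134 (p = 0.0317), each with an adjusted p of 0.341 over 43 scores. The hypoxia list had a median log2 fold change of -0.01, with 6 of 13 members positive. For insulin and IGF 12 of 15 were positive, and for matrix 18 of 26.

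All samples are labelled male. Xist, the non-coding RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254), had 8061 counts in bone marrow HFD library 1_3, at most 8 in the other bone marrow libraries and at most 120 in adipose. Y-linked genes varied between bone marrow libraries, with Uty at 5 to 5492 counts (5492 in the same library), Ddx3y at 20 to 9117, Eif2s3y at 4 to 6854 and Kdm5d at 0 to 1742. In adipose they had at least 1024, 8139, 587 and 133 counts in every library.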
